A study of Mus musculus with 6 samples.

How the data were processed

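RNA sequencing was carried out on gonads of male mouse embryos at E13.5 (embryonic day). There were 3 wild-type libraries and 3 libraries from embryos lacking both prostaglandin D synthases, L-Pgds (gene Ptgds) and H-Pgds (gene Hpgds), and the labels describe the gonads as coming from 6 different littermates, so each library was taken as a separate embryo. Libraries keep the numbers of the labels: 1, 3 and 4 for wild type and 5, 7 and 8 for knockout. The labels do not say which libraries shared a litter, and they give no batch or pairing.

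The deposited table gives for each gene a signal that the authors made from their reads, namely upper-quartile normalised pseudo-counts. These are adjusted, fractional values and not reads. Per the submitters' processing notes, the authors used CASAVA 1.8.2 and edgeR 2.6.2 and the genome build mm9; the role of each tool and the gene annotation are not given in the sources used here. Coordinates below are those of the deposited table, on mm9, counted from 1: in a match to annotated transcripts, the spans of 4995 genes fitted a start counted from 1 and those of 24 genes a start counted from 0. The upper quartile was 1484 or 1485 in each library, and the values summed to between 22881124 and 23734462 in wild type and between 21657342 and 21846849 in knockout. These sums follow from the normalisation and are not sequencing depths. Whole reads were not recovered from the values, so the depth is unknown, no interval for counting error is given, and no count model was run. All 6 columns of values were matched to a library by their names, which left 0 columns unmatched.

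Values were analysed as log2(value + 1) with limma 3.58.1 in R 4.3.3, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Fold changes are on this scale, which understates the change of genes with low values. Of 16862 genes in the table, 15116 with a value of at least 10 in at least 3 libraries were tested. Knockout was compared with wild type by limma's moderated test with a mean-dependent prior on the spread, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Adjusted p-values of genes below come from this test. An exact permutation test of a single gene with 3 against 3 libraries cannot go below p = 0.1.

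The 24 gene lists held cell type markers and pathways, and they were fixed before the data were examined, as were the tests, the alternative settings and the rule for named genes. Lists with at least 5 measured members, 23 in all, were tested with limma's camera with a preset correlation between genes of 0.01, and with Benjamini-Hochberg adjustment over these lists. The tests were repeated with a correlation estimated from the data and with fry, which tests whether the genes of a list move, on balance, one way. Members were also counted with p-values adjusted over the list alone. The rule named both targeted genes, a preset group of gonad genes, the 10 genes with the highest rise and the 10 with the deepest fall among genes past the threshold with knockout and wild-type libraries fully apart, and up to 3 members past the threshold from each list (at most 2 by mean level where none passed). A gene that the rule names is not reported here. Genes within 5 Mb of Ptgds or Hpgds were compared with all others by Fisher's exact test, two-sided.

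The alternative settings fixed beforehand were pseudocounts of 0.5, 5 and 10, no filter, a stricter filter at 50, scaling by the median of ratios or to equal totals, quantile normalisation, library weights, a robust prior, no mean-dependent prior, each library left out in turn, a threshold of 0.1, a limit of at least 2-fold, and a distance of 10 Mb for neighbours. After the data were seen, an alternative was added that removed, in each library, the trend of the log2 values on transcript length and GC content with natural splines of 4 degrees of freedom each, alone and with wild-type library 1 left out. Length and GC content were those of the longest protein-coding transcript of each gene in the GENCODE vM21 annotation of GRCm38, matched by gene identifier and used without its coordinates; 14602 genes (96.6%) had both.

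The tests were tried on simulated data built on the knockout against wild-type comparison. With no trend and 15116 genes, 80.0% of genes changed 2-fold and 46.0% of genes changed 1.5-fold were recovered, with 11 false calls among 137. With a length and GC trend added, 7406 of 7564 calls were false. With removal of that trend on 14602 genes, 79.2% and 48.0% were recovered, with 6 false calls among 129. The added trend was a straight line in log2 length and in GC content, the same variables that the removal fits. Its removal was therefore bound to work, and the result does not show how well removal works on the trend in the data. For the list test, the 1 shifted list was called and 0 of 20 unshifted lists were. The simulated genes were drawn independently, so this does not show how often the test errs for lists whose genes move together. In the data, the estimated correlation between genes was 0.97 in the muscle list.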

Results

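Gene expression was measured by RNA sequencing in gonads of male mouse embryos at E13.5, a stage in embryonic days when Sertoli cells have enclosed the germ cells in cords and the germ cells are leaving the cell cycle. The study asked what prostaglandin D2, made by the enzymes L-Pgds and H-Pgds, does for the differentiation of fetal male germ cells. It compared 3 wild-type libraries with 3 libraries from embryos lacking both enzymes. Summed normalised values lay between 21657342 and 23734462 per library. Of the 16862 genes listed, 15116 passed the filter. No 2 libraries held identical values.

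Ptgds, which encodes L-Pgds, was almost lost in the knockout. Its normalised value averaged 7803 ± 1110 (SD, n = 3) in wild type and 7.39 ± 6.81 (SD, n = 3) in knockout, a log2 change of -10.15 (SE 0.42, limma adjusted p = 3.41e-06). The 3 knockout libraries held 15.2, 4.0 and 2.94, and the lowest wild-type library held 6560. Ptgds (NCBI gene 19215) lies on chromosome 2 from 25322232 to 25325269 in mm9. Hpgds, which encodes H-Pgds, was higher in the knockout, at 92.9 ± 9.32 against 49.2 ± 5.21 (SD, n = 3 each), a log2 change of 0.91 (SE 0.21, adjusted p = 0.00853). With the trend on transcript length and GC content removed, its log2 change was 0.60 (SE 0.22, adjusted p = 0.108). Hpgds (NCBI gene 54486) lies on chromosome 6 from 65067287 to 65094724. The deleted part of the gene is not given in the labels, so a value over the whole gene does not check the H-Pgds side of the genotype.

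**Figure D1:**
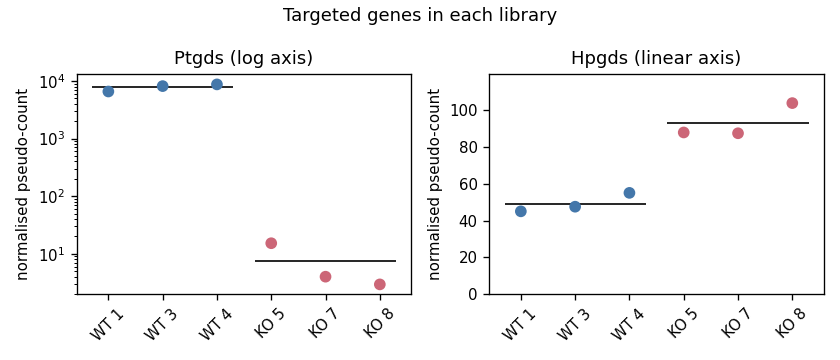
Normalised pseudo-counts of Ptgds (log axis) and Hpgds (linear axis) in each of the 6 libraries, with points for libraries (WT, wild type; KO, knockout) and lines for group means. Ptgds lay at or above 6560 in wild type and at or below 15.2 in knockout, while Hpgds was higher in all 3 knockout libraries.

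Among the 10 genes with the steepest rises were Rest and its partner. Rest, a repressor of neuronal genes, rose from 72.9 ± 32.7 to 510 ± 57.2 (SD, n = 3), and Rcor1, which encodes the corepressor CoREST, rose from 54.2 ± 19.0 to 317 ± 47.9. Peg3, an imprinted zinc finger gene expressed from the paternal allele, rose 7.08-fold (log2 2.82, SE 0.27, adjusted p = 0.000744). Nhs, mutated in a syndrome of congenital cataract, had the highest rise, 9.87-fold (log2 3.30, SE 0.29). Cpeb4, Shroom4, Zbed6, Zbtb38 and Adamts6 rose between 6.15-fold and 9.29-fold. Zbed6 lies inside the Zc3h11a gene, so its reads are uncertain. The other 9 of the 10 deepest falls were shallower than that of Ptgds, in genes with a wild-type mean of at most 128. Capn9, a calpain protease, fell from 81.9 ± 12.6 to 26.3 ± 3.86, and Rnase12 fell from 69.8 ± 8.06 to 22.6 ± 10.3. Pnliprp1, Elane (neutrophil elastase), Mb (myoglobin), Slc14a1, Fhad1, Crct1 and Kcnn4 had log2 changes between -2.04 and -1.56. Without wild-type library 1, the adjusted p was 0.0775 for Mb, 0.0843 for Pnliprp1 and 0.0829 for Fhad1. Without at least 1 of the other libraries, calls also ended for these 3 (adjusted p up to 0.113), for Slc14a1 (up to 0.0865) and for Kcnn4 (up to 0.065). The log2 change without wild-type library 1 moved from -2.04 to -1.10 for Pnliprp1 and from -1.78 to -1.16 for Mb.

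In all, 5180 of 15116 genes (34.3%) changed, 2609 of them higher and 2571 lower in the knockout. A change of at least 2-fold was seen for 357 of the higher genes and 104 of the lower ones. In 7607 genes (50.3%) the libraries of both genotypes did not overlap. For a single gene the chance of this is 10%. Genes are not independent and can move together with a trend between libraries, so the share over genes does not measure chance. Without wild-type library 1, which stood apart from the others, 4506 genes changed (2350 higher, 2156 lower), and without wild-type library 4 the count was 3032. With values scaled to equal totals, 3511 genes were higher and 1690 lower, a share of 67.5% higher against 50.4%.

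The genes that rose had long, AT-rich transcripts and those that fell had short, GC-rich ones. The median transcript length was 5191 nt for higher genes, 1710 nt for lower genes and 3086 nt for the rest, and the median GC content was 45.4%, 55.4% and 50.5%. Among 5 groups of equal size by length, the shortest had 18 genes higher and 1330 lower, while in the longest 1328 were higher and 50 lower. Across genes, which are not independent replicates, length and GC content accounted for 41.8% of the variance of the log2 change. With the trend removed, an alternative chosen after seeing the data, 1653 of 14602 genes changed (813 higher, 840 lower). Of the 5115 changed genes with a length and GC value, 1083 remained past the threshold in the same direction, 693 of them higher and 390 lower. Rest, Rcor1, Peg3, Nhs and Ptgds were among those that remained, with log2 changes of 2.47, 2.25, 2.37, 2.79 and -9.55 after removal. Of 85 named genes past the threshold, 37 were so in the same direction after removal. Of the 48 whose call ended, 12 had a log2 change that moved by at most 1.5 times, so a lost call does not by itself show that the change followed the trend. Among these 12 were Adamts6 (2.62 to 2.13, adjusted p = 0.0532), Fhad1 (-1.74 to -1.87, 0.0569), Pnliprp1 (-2.04 to -1.75, 0.122), Elane (-1.82 to -1.22, 0.0985), Mb (-1.78 to -1.26, 0.148) and Kcnn4 (-1.56 to -1.12, 0.0807), while Crct1 moved further (-1.68 to -1.04, 0.0908).

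**Figure D2:**
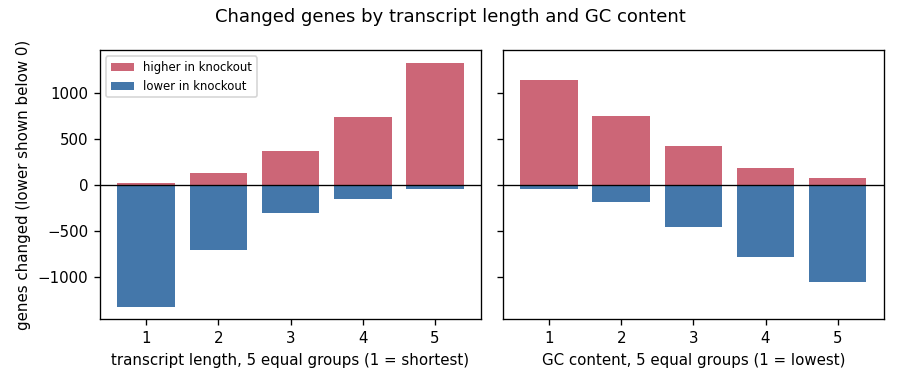
Number of genes higher (above 0) and lower (below 0) in the knockout, in 5 groups of equal size by transcript length and by GC content. Higher genes were most frequent among the longest transcripts (1328 genes) and lower genes among the shortest (1330 genes).

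With all libraries, no member of the male germ cell differentiation list passed the test, and Ddx4 was the one general germ cell marker past it. Both counts depended on the libraries included. Nanos2, which directs germ cells to the male fate, averaged 297 ± 434 in wild type and 64.9 ± 37.7 in knockout (SD, n = 3; log2 -1.01, SE 0.92, adjusted p = 0.417). Wild-type library 1 held 798 and the other 5 libraries between 37.4 and 108, and the log2 change without it was 0.35 (adjusted p = 0.495). Of the 17 measured members of this list, 0 rose and 0 fell over all genes or adjusted over the list alone in limma's test (camera adjusted p = 0.92, fry adjusted p = 0.97), and 2 members, Dnmt3a and Lefty2, had an unadjusted p under 0.05. The list had 2 members higher without wild-type library 1, Piwil2 (log2 0.42, SE 0.14, adjusted p = 0.0345) and Tdrd1 (log2 0.72, SE 0.22, adjusted p = 0.0222), and Lefty2 was higher without knockout library 8 (adjusted p = 0.0436). Without wild-type library 3, Dnmt3a was higher (0.0339) and Gtsf1 lower (0.0335), and without each of the other 3 libraries 0 members passed. Members outside the rule are named here after their values were seen. The list test without wild-type library 1 pointed up and did not pass (camera adjusted p = 0.33, and 0.057 with the trend also removed). After removal of the length and GC trend 1 member rose, Pld6 (log2 0.60, adjusted p = 0.0366), named after its value was seen. Dnmt3a, a DNA methyltransferase, stood at 4474 ± 386 in wild type and 5322 ± 251 in knockout (adjusted p = 0.0531), and Lefty2, a Nodal antagonist, at 1676 ± 247 and 2079 ± 296. Dnmt3l and Stra8 were below the filter, with 45.2 and 44.2 in wild-type library 1 and at most 9.04 and 11.3 in the others. Ddx4, an RNA helicase of germ cells, rose from 2709 ± 444 to 3800 ± 822 (adjusted p = 0.037) and was the 1 member of 16 in the general germ cell list to change. Its log2 change went from 0.48 (SE 0.16) to 0.27 (SE 0.12, adjusted p = 0.177) with the trend removed, and its adjusted p was 0.108 without wild-type library 3, 0.114 without wild-type library 4, 0.0702 without knockout library 5 and 0.103 without knockout library 7 (log2 0.31). The call was kept without wild-type library 1 (log2 0.61, SE 0.15, adjusted p = 0.00846; 0.38 and 0.0328 with the trend also removed), where Rnf17 and Stk31 were also higher (adjusted p = 0.00808 and 0.0494), and without knockout library 8. Without wild-type library 3, 4 other members were lower: Dnd1, Nanos3, Tex101 and Gtsf1 (adjusted p from 0.0137 to 0.0335). Adjusted over the list alone, 0 members passed (camera adjusted p = 1; without wild-type library 1 it was 0.33, pointing up, and 0.085 with the trend also removed).

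Among pluripotency genes, 5 of 24 rose and 2 fell, and adjusted over the list alone 5 rose and 1 fell (camera adjusted p = 0.79). With 1 library left out, 2 to 5 rose and 0 to 4 fell. With the length and GC trend removed, 2 were higher and 0 lower and the list pointed up without passing (adjusted p = 0.071), and with wild-type library 1 also left out 4 were higher and 0 lower (adjusted p = 0.05, not past the threshold). Sox2 rose from 619 ± 50.2 to 905 ± 158 and Klf4 from 154 ± 14.2 to 229 ± 24.8, both also past the threshold after removal of the length and GC trend (adjusted p = 0.00961 and 0.0172). Kit, the stem cell factor receptor, rose from 1085 ± 268 to 1796 ± 48.4, and L1td1 rose 1.65-fold, and both lost their calls after that removal, Kit with a log2 change from 0.76 to 0.47 (adjusted p = 0.0752) and L1td1 with one about as large, from 0.73 (SE 0.22) to 0.66 (SE 0.23, adjusted p = 0.0995). The log2 change of L1td1 moved from 0.73 to 0.41 without wild-type library 1. Pou5f1 stood at 4695 ± 671 in wild type and 3776 ± 243 in knockout (adjusted p = 0.0548, and 0.0163 without wild-type library 3). With the trend removed, the log2 change of Pou5f1 turned from -0.31 to 0.23 (adjusted p = 0.106). With wild-type library 1 also left out, Pou5f1 was higher in knockout and past the threshold. Nanog stood at 29.2 ± 7.19 and 41.2 ± 7.66 (adjusted p = 0.211). In the meiosis list 4 of 22 members rose and 1 fell, with 0 adjusted over the list alone (camera adjusted p = 0.79). The counts were 7 and 2 without wild-type library 1, where the list pointed up and did not pass (adjusted p = 0.33, and 0.057 with the trend also removed), and 0 to 4 and 0 to 2 without each other library. Hormad1, a protein of the meiotic chromosome axis, rose from 162 ± 31.0 to 289 ± 113, and Rec8, a meiotic cohesin, fell from 333 ± 72.3 to 210 ± 30.6. With the trend removed, Hormad1 was past the threshold and Rec8 was not (adjusted p = 0.0267 and 0.267). The call of Hormad1 ended without wild-type library 3 (adjusted p = 0.101), wild-type library 4 (0.107), knockout library 5 (0.0782) or knockout library 7 (0.119, with the log2 change from 0.78 to 0.48), and that of Rec8 without knockout library 5 (0.0769) or 7 (0.059). Klf4 did not pass without wild-type library 4 (0.0701), knockout library 5 (0.0637) or knockout library 7 (0.0622), nor L1td1 without knockout library 5 (0.0858) or 7 (0.0878). Sycp3 stood at 241 ± 116 and 238 ± 130. Wild-type library 1 also had higher values of the general germ cell list than the other wild-type libraries, by a median of 0.97 on the log2 scale.

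The cell cycle inhibitors Cdkn1a (p21) and Cdkn1c (p57) fell, each by 1.61-fold in the ratio of wild type to knockout (adjusted p = 0.0163 and 0.0109). Cdkn1c went from 12720 ± 3730 to 7712 ± 392. Rbl2, a retinoblastoma relative, rose 1.61-fold, and Cdkn1b (p27) stood at 962 ± 54.1 and 1077 ± 51.3 (adjusted p = 0.193). Of 14 members, 2 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 1). Among proliferation genes, Mki67, Ccne2 and Ccnd2 rose 1.54-fold, 1.81-fold and 1.56-fold, within 6 of 30 members that rose and 5 that fell, and again 6 and 5 adjusted over the list alone (camera adjusted p = 0.92). With 1 library left out, 4 to 6 of these genes rose and 0 to 5 fell, and of the inhibitors 2 to 3 rose and 1 to 3 fell. Without wild-type library 1 the log2 change of Cdkn1a moved from -0.69 to -0.45 and that of Cdkn1c from -0.68 to -0.46, and without knockout library 5 the adjusted p of Cdkn1a was 0.0547. With the trend removed, Cdkn1a, Cdkn1c, Rbl2, Mki67, Ccne2 and Ccnd2 were not past the threshold (adjusted p = 0.161, 0.34, 0.126, 0.215, 0.179 and 0.176). Of all proliferation genes 0 were then higher and 2 lower, and of the inhibitors 0 were higher and 1 lower.

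Sertoli cell and fetal Leydig cell markers went both ways. Sox9, which drives Sertoli cell differentiation, stood at 1931 ± 424 in wild type and 2236 ± 99.8 in knockout (log2 0.24, SE 0.15, adjusted p = 0.236; log2 0.04 without wild-type library 1), and Amh, the hormone that removes the Mullerian duct, at 63890 ± 9900 and 49260 ± 11700 (adjusted p = 0.131). Amh was lower without wild-type library 1 (log2 -0.52, SE 0.19, adjusted p = 0.0496), while with the trend removed its log2 change was 0.12 (adjusted p = 0.702). Of 25 Sertoli cell genes, 4 rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 1), and 1 to 4 rose and 2 to 5 fell with 1 library left out. Clu fell from 31230 ± 3670 to 18900 ± 4530, Etd from 644 ± 85.1 to 377 ± 130, and Erbb4 rose from 3.35 ± 2.94 to 16.9 ± 2.89. With the length and GC trend removed, Etd was past the threshold (adjusted p = 0.0463), while Clu (log2 -0.74 to -0.34, 0.134) and Erbb4 (1.65 after removal, 0.103) were not. Etd did not pass without wild-type library 4 (0.0622) or knockout library 5 (0.0568), nor Erbb4 without knockout library 8 (0.0521). Of 16 fetal Leydig cell genes, 1 rose and 3 fell, and 0 passed adjusted over the list alone (camera adjusted p = 0.49). The number that fell was 0 without wild-type library 1, wild-type library 4 or knockout library 5, 1 without knockout library 7, 5 without wild-type library 3 and 6 without knockout library 8. Ren1 and Fdx1 fell and Prlr rose, though without wild-type library 1 the adjusted p was 0.0547 for Ren1 and 0.0704 for Fdx1. The calls of Ren1, Fdx1 and Prlr also ended without wild-type library 4, knockout library 5 or knockout library 7 (adjusted p from 0.065 to 0.118), and that of Prlr without wild-type library 3 (0.0849). With the trend removed, Fdx1 was past the threshold (adjusted p = 0.0375), while Ren1 (log2 -0.84 to -0.42, 0.255) and Prlr (0.41 to -0.25, 0.151) were not. Cyp11a1, the first enzyme of steroid synthesis, stood at 25100 ± 8150 and 16560 ± 3610 (log2 -0.57, adjusted p = 0.059). Wild-type library 1 held 34450 and the other wild-type libraries 19556 and 21286, and without it the log2 change of Cyp11a1 was -0.32 (adjusted p = 0.137), while Cyp11a1 passed without wild-type library 3 (adjusted p = 0.0314) or knockout library 8 (0.0334). Insl3 stood at 1463 ± 437 and 1194 ± 540 (adjusted p = 0.37).

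In the interstitial and peritubular list, Ptch1, the Hedgehog receptor and a target of the pathway, rose 5.62-fold, from 135 ± 34.8 to 762 ± 193, and its log2 change was 2.17 after removal of the length and GC trend (adjusted p = 0.00194). Other Hedgehog pathway genes, named after their values were seen, did not pass. Gli1 stood at 3098 ± 104 and 3037 ± 373 (adjusted p = 0.808), and Dhh at 4501 ± 816 and 4201 ± 552 (adjusted p = 0.646). Activity of the pathway was not tested. Des and Actg2, genes of contractile cells, fell from 2405 ± 1530 to 841 ± 75.4 and from 146 ± 69.2 to 55.9 ± 5.83. Wild-type library 1 held Des at 4176 and the other wild-type libraries at 1447 and 1593, and without it the log2 change of Des moved from -1.34 to -0.86 (adjusted p = 0.000636). Actg2 lost its call after removal of the trend (log2 -1.27 to -0.86, adjusted p = 0.0706). Of 21 members 6 rose and 5 fell, and 7 and 7 adjusted over the list alone (camera adjusted p = 0.92). Endothelial genes went both ways, with 3 of 15 higher and 5 lower, and 4 and 5 adjusted over the list alone (camera adjusted p = 0.92), and 3 to 4 higher and 2 to 5 lower with 1 library left out. Erg, Flt1 and Kdr rose 2.11-fold, 2.07-fold and 1.73-fold, and Kdr lost its call after removal of the trend (log2 0.79 to 0.50, adjusted p = 0.0574). Among ovarian somatic genes, Wnt4, which supports ovarian development, fell from 3807 ± 293 to 2183 ± 125 (log2 -0.80, SE 0.09, adjusted p = 0.000969), and -0.77 after removal of the trend. Rspo1 fell from 1059 ± 51.1 to 723 ± 30.9 and Lef1 rose from 173 ± 51.9 to 325 ± 13. The fall of Rspo1 shrank from -0.55 to -0.08 with the trend removed, which ended its call (adjusted p = 0.594), while Lef1 was still past the threshold (adjusted p = 0.0204). This list had 1 of 14 higher and 2 lower, and the same adjusted over the list alone (camera adjusted p = 0.79).

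Of 15 measured macrophage and leukocyte genes, 9 fell in the knockout and 0 rose, with the same counts adjusted over the list alone. The complement genes C1qa and C1qb fell 2.13-fold and 2.22-fold, from 599 ± 117 to 278 ± 12.8 and from 740 ± 144 to 330 ± 42.9, and Coro1a, an actin regulator of leukocytes, fell from 567 ± 75.5 to 251 ± 16.0 (SD, n = 3). The other 6 did not pass, among them (named after their values were seen) Cx3cr1 at 127 ± 3.27 and 124 ± 17.4, Mrc1 at 163 ± 43.7 and 176 ± 29.7, and Ptprc at 35.4 ± 3.25 and 37.5 ± 3.74. The list passed the test (camera adjusted p = 0.0021, fry adjusted p = 0.034), but not with an estimated correlation (p = 0.15, adjusted p = 1). After removal of the length and GC trend 5 members were lower, the median log2 change went from -0.69 to -0.46, and the list passed with the preset correlation (adjusted p = 0.00016) but not with an estimated one (p = 0.078, adjusted p = 0.77). In wild-type library 1 this list stood above the other wild-type libraries by a median of 0.31 on the log2 scale. Without that library the adjusted p was 0.0029, with 7 members lower, and without each other library 6 to 9 members were lower.

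Of 17 measured retinoic acid genes, 9 fell and 1 rose, and 10 and 1 adjusted over the list alone, but after removal of the length and GC trend 2 were lower and 1 higher, and the median log2 change went from -0.37 to -0.18. The list passed with the preset correlation (camera adjusted p = 0.033) and with fry (adjusted p = 0.017) but not with an estimated one (p = 0.04, adjusted p = 0.91), and not after removal of the length and GC trend (adjusted p = 0.064), without wild-type library 3 (0.065), without knockout library 5 (0.085) or with quantile normalisation (0.056). With 1 library left out, 5 to 7 members fell and 0 to 1 rose. Crabp2, which binds retinoic acid inside cells, fell from 673 ± 128 to 340 ± 7.92, and the receptor Rxrg fell from 90.4 ± 55.3 to 36.9 ± 11.4. Without wild-type library 1 the log2 change of Rxrg moved from -1.15 to -0.69 (adjusted p = 0.0914), its adjusted p was 0.0541 without wild-type library 4 and 0.114 without knockout library 7 or 8, and with the trend removed its log2 change was -0.84 (adjusted p = 0.173). Cyp26b1, which degrades retinoic acid and keeps it from male germ cells, rose from 2673 ± 686 to 3986 ± 571 (log2 0.60, SE 0.17, adjusted p = 0.0223). Its log2 change was 0.40 without wild-type library 1, and its adjusted p was 0.0343 with the trend removed, 0.0604 without wild-type library 4 and 0.0789 without knockout library 8. Members that fell do different things: Aldh1a2 makes retinoic acid, Stra6 takes up retinol, and Rarg, Rxrb and Rxrg are receptors.

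Genes of the other prostaglandin pathways fell more often than they rose, with 6 of 20 lower and 1 higher, and the same adjusted over the list alone, and the list passed with fry (adjusted p = 0.026) but not in the main list test (camera adjusted p = 0.49). With 1 library left out, 4 to 7 were lower. After removal of the length and GC trend 3 were lower and 0 higher (camera adjusted p = 0.082). Ptger3, a prostaglandin E receptor, fell from 26.9 ± 2.77 to 11.3 ± 2.29, Ptgis, which makes prostacyclin, from 1907 ± 472 to 1035 ± 67.1, and Tbxa2r, the thromboxane receptor, from 986 ± 117 to 602 ± 118. Ptger3 did not pass without wild-type library 4 (adjusted p = 0.075) or knockout library 5 (0.0666). Tbxa2r lost its call after removal of the length and GC trend (log2 -0.72 to -0.26, adjusted p = 0.152). The prostaglandin D2 receptors Ptgdr and Ptgdr2 were not found by name among the genes listed, so they could not be analysed.

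**Figure D3:**
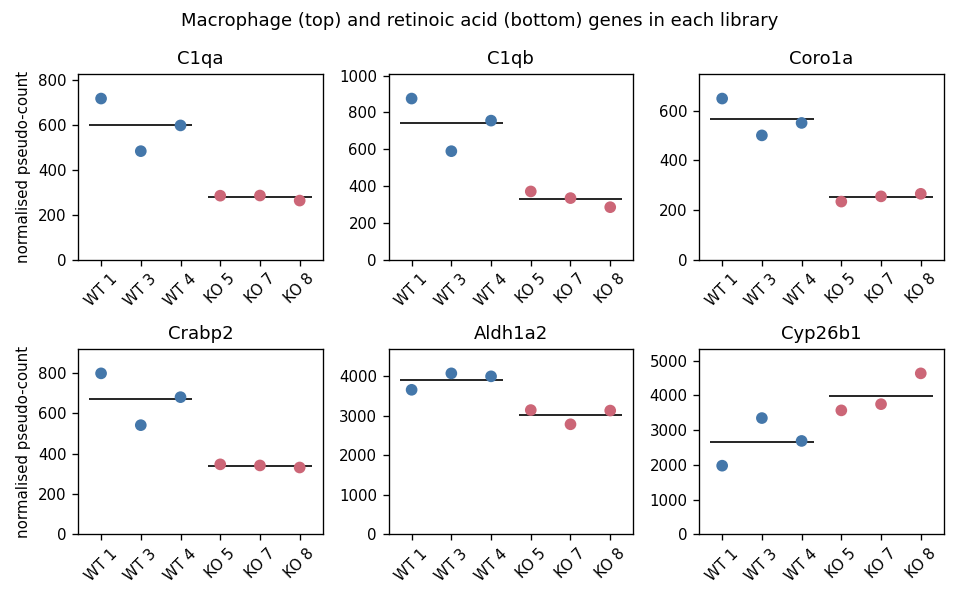
Normalised pseudo-counts (linear axes from 0) of C1qa, C1qb and Coro1a (top) and of Crabp2, Aldh1a2 and Cyp26b1 (bottom) in each library, with points for libraries (WT, wild type; KO, knockout) and lines for group means. C1qa averaged 599 in wild type and 278 in knockout, and Cyp26b1 2673 and 3986.

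The Nodal and TGF-beta list had 8 of 26 members higher and 4 lower, and the same adjusted over the list alone (camera adjusted p = 0.49), with 5 to 9 higher and 3 to 4 lower when 1 library was left out. Inhba, an activin subunit, rose from 14.7 ± 6.78 to 58.9 ± 13.6, and the receptors Acvr1b and Acvr2a rose 2.19-fold and 1.70-fold. In cholesterol synthesis 1 of 18 rose and 4 fell, and the same adjusted over the list alone (camera adjusted p = 0.92), with Idi1 higher and Pmvk and Mvk lower. Without wild-type library 1, 4 of these genes were higher and 4 lower, and the list pointed up without passing (adjusted p = 0.58); without each other library 1 to 2 were higher and 2 to 5 lower. Of 15 immediate early and heat shock genes 1 rose and 5 fell, and 1 and 6 adjusted over the list alone (camera adjusted p = 0.49), with 0 to 1 higher and 1 to 6 lower when 1 library was left out. Hspb1, Ier3 and Jund fell 1.90-fold, 1.53-fold and 1.33-fold. Of 17 hypoxia and glycolysis genes 1 rose and 4 fell, and 1 and 3 adjusted over the list alone (camera adjusted p = 0.49), with 1 to 2 higher and 2 to 4 lower when 1 library was left out. Vegfa rose from 1660 ± 201 to 2613 ± 168, and the glycolysis genes Tpi1 and Ldha fell 1.48-fold and 1.37-fold. After removal of the length and GC trend, 4 members were higher and 1 lower in the Nodal and TGF-beta list. In cholesterol synthesis 0 passed either way. The immediate early and heat shock list and the hypoxia and glycolysis list each had 1 higher and 0 lower. The median log2 change of these lists turned, from -0.20 to 0.09 and from -0.21 to 0.07. With the length and GC trend removed, Inhba, Acvr1b and Vegfa were past the threshold, while Acvr2a, Idi1, Pmvk, Mvk, Hspb1, Ier3, Jund, Tpi1 and Ldha were not (adjusted p from 0.081 to 0.678). Idi1 kept most of its log2 change (1.22 to 0.98), and the others moved by over 1.5 times. Without knockout library 5 the adjusted p was 0.0508 for Idi1, 0.0633 for Ier3 and 0.0711 for Jund, and for Jund it was 0.0907 without wild-type library 4 and 0.0551 without knockout library 7.

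No list of markers of tissues next to the gonad passed the test with all libraries. Of 13 mesonephric epithelium genes 1 rose and 2 fell, and the same adjusted over the list alone (camera adjusted p = 0.21); Lhx1 rose from 56.2 ± 15.5 to 158 ± 8.90, while Krt19 and Cldn3 fell 2.14-fold and 2.32-fold. Without wild-type library 1 this list passed (adjusted p = 0.04), with 6 members lower against 2 without each other library, and with the trend also removed it did not (adjusted p = 0.085). Of 14 muscle genes 1 fell, Tnni1, and the same adjusted over the list alone (camera adjusted p = 0.09). The number that fell was 4 without wild-type library 1, 10 without wild-type library 3 and 1 without each other library. These genes stood above the other wild-type libraries in wild-type library 1, by a median of 5.03 on the log2 scale. Of 10 erythroid genes 2 fell, Klf1 and Gata1, and 1 adjusted over the list alone (camera adjusted p = 0.59), and 0 to 6 fell with 1 library left out. In the neural list 2 of 12 fell, Tubb3 and Hand2, and the same adjusted over the list alone (camera adjusted p = 0.79), and 2 to 4 fell with 1 library left out. In the adrenal cortex list 2 of 6 fell, Mrap and Akr1b7, and the same adjusted over the list alone (camera adjusted p = 0.2), and 1 to 3 fell with 1 library left out. With the length and GC trend removed, Lhx1 and Krt19 were past the threshold, while Cldn3, Tnni1, Klf1, Gata1, Tubb3, Hand2, Mrap and Akr1b7 were not (adjusted p from 0.0868 to 0.391). Gata1 kept most of its log2 change (-1.26 to -0.89), and the others moved by over 1.5 times. Without wild-type library 4 the adjusted p was 0.143 for Gata1, 0.0529 for Klf1 and 0.0505 for Akr1b7, and for Gata1 it was 0.115 without knockout library 5 and 0.13 without knockout library 7. The log2 change of Tnni1 moved from -1.13 to -0.73 without wild-type library 1.

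**Figure D4:**
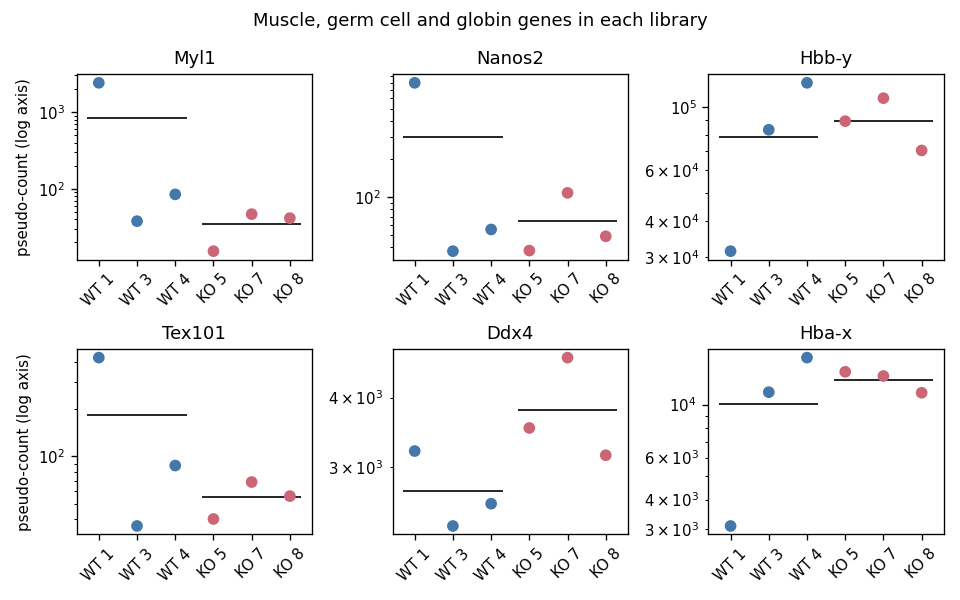
Normalised pseudo-counts (log axes) of Myl1, Nanos2, Hbb-y, Tex101, Ddx4 and Hba-x in each library, with points for libraries (WT, wild type; KO, knockout) and lines for group means. Myl1 stood at 2407 in wild-type library 1 and between 15.4 and 84.7 in the others, and Hbb-y at 31370 against 70416 to 121170.

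All 4 measured Y-linked genes rose, too few for a list test, and 4 rose adjusted over the list alone. Kdm5d, Uty and Ddx3y rose 1.90-fold, 1.88-fold and 1.69-fold, and Eif2s3y rose from 1442 ± 164 to 2032 ± 386. After removal of the length and GC trend, 1 of the 4, Eif2s3y, was past the threshold (adjusted p = 0.0201).

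In the main test, genes near the targeted loci changed about as often as other genes. Within 5 Mb of Ptgds or Hpgds, 54 of 155 genes changed (34.8%), 16 higher and 38 lower, against 34.3% elsewhere (odds ratio 1.03, Fisher's exact test, two-sided, p = 0.87). Around Ptgds 53 of 144 genes changed, and around Hpgds 1 of 11. Within 10 Mb the odds ratio was 1.04 (exact p = 0.76), and with the length and GC trend removed it was 0.627 within 5 Mb (exact p = 0.15). The odds ratios of the 2 loci then lay on different sides of 1, without passing the threshold. Near Ptgds 9 of 138 genes within 5 Mb changed (0.544, exact p = 0.079), and near Hpgds 2 of 10 (1.96, exact p = 0.32). Within 10 Mb it was 23 of 224 near Ptgds (0.895, exact p = 0.75) and 12 of 63 near Hpgds (1.85, exact p = 0.069). For both loci within 10 Mb the odds ratio was 1.09 (exact p = 0.64).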

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

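Removal of the length and GC trend, alone or with wild-type library 1 left out, was chosen only after the result was seen; the other alternatives were planned. No paired analysis was possible because the library numbers are not shared between the groups. A count model was planned only if the values were raw counts, and none was run because whole reads were not recovered. Depth is unknown, so what it limits cannot be stated. With each library left out in turn, changed genes ranged from 3032 to 5041, higher genes from 1635 to 2495 and lower genes from 1397 to 2546, with the lowest counts without wild-type library 4. With a limit of 2-fold, 461 genes changed (357 higher, 104 lower), since fewer genes could pass. With equal totals 1690 genes were lower, and that scaling moved the median log2 change by 0.10, while other scalings moved it by at most 0.01. With the length and GC trend removed, 1653 genes changed (813 higher, 840 lower), and with wild-type library 1 also left out 1777 (780 higher, 997 lower); 1083 and 1119 of the main calls were kept and 8 and 16 turned. Hpgds kept its direction but not its call, at 0.60 and 0.53 (log2), while Ptgds kept both in every setting run. The lists past the threshold numbered 1 with quantile normalisation, 1 without knockout library 5, 1 after trend removal with or without wild-type library 1, and 0 with an estimated correlation; they ranged from 1 to 3 with each library left out and numbered 3 with fry. The odds ratio for neighbours, never past the threshold, lay on the other side of 1 with pseudocounts of 5 (0.996) and 10 (0.999), with no filter (0.992), without wild-type library 4 (0.917, in a range up to 1.23 over the libraries left out), and after trend removal (0.627, and 0.693 with wild-type library 1 left out). Of 1771 comparisons for named genes, 1543 kept direction and side of the threshold, 187 lost the call, 20 gained it and 21 turned. With 1 library left out, 26 named genes lost the call at least once: Akr1b7, Cdkn1a, Cyp26b1, Ddx4, Erbb4, Etd, Fdx1, Fhad1, Gata1, Gm1564, Hormad1, Idi1, Ier3, Jund, Kcnn4, Klf1, Klf4, L1td1, Mb, Pnliprp1, Prlr, Ptger3, Rec8, Ren1, Rxrg and Slc14a1. Over the libraries left out, Nanos2 ranged from -1.83 to 0.35 and Sycp3 from -0.47 to 0.31. Sycp3 turned with equal totals (0.05), without wild-type library 1 (0.31), knockout library 5 (0.05) and knockout library 8 (0.26), and Nanos2 without wild-type library 1 (0.35). After trend removal Amh (0.12), Cdkn1b (-0.23), Pou5f1 (0.23), Insl3 (0.35), Prlr (-0.25), Dnmt3a (-0.05) and Jund (0.09) turned. With wild-type library 1 also left out, Sox9 (-0.15), Cdkn1b (-0.19), Nanos2 (0.67), Pou5f1 (0.28), Sycp3 (0.20), Insl3 (0.52), Prlr (-0.23), Dnmt3a (-0.08) and Jund (0.05) turned, Pou5f1 with an adjusted p of 0.0474. For these changes the cause was not tested, except for length and GC content, below.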

Other observations

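The gene families and library values in this and the next paragraph, and all tests of explanations after them, were chosen after the result was seen. Of 9 gene families taken by the start of their symbols, with no enrichment test, 4 had many members lower. Their median transcript lengths were 926 nt to 1581 nt, and among all genes the shortest of the 5 length groups had 1330 of 2921 lower. Their median GC contents were 49.7% to 51.5%, against 50.5% for unchanged genes. With the length and GC trend removed, the median log2 changes of these 4 families lay between -0.09 and -0.06. Of 76 mitochondrial ribosomal protein genes 54 were lower and 0 higher, with a median log2 change of -0.43, of 41 complex I subunits 27 were lower and 1 higher, and of 78 cytosolic ribosomal protein genes 41 were lower and 0 higher. Proteasome subunits had 20 of 39 lower and 1 higher. Of 344 Zfp zinc finger genes 114 were higher and 26 lower, and of 36 kinesins 15 were higher and 0 lower. The other 3 moved less: collagens, with the longest median transcript of the 9 (6119 nt), had 8 of 41 higher and 0 lower and a median of 0.03, Hox genes 3 of 30 higher and 1 lower, and histones 0 of 30 higher and 3 lower. The histones had the shortest median transcript of the 9 (742 nt, median GC content 54.3%) but a median log2 change of 0.01. The medians of all 9 kept their sign with equal totals, median of ratios and quantile scaling, though without wild-type library 1 that of the histones was -0.08, and with the trend removed those of collagens and Hox genes were -0.04 and 0.13. After removal of the length and GC trend, 19 mitochondrial ribosomal protein genes, 2 complex I subunits, 6 cytosolic ribosomal protein genes and 2 proteasome subunits were lower, 24 Zfp genes were higher and 14 lower, 4 kinesins were higher and 1 lower, and 1 collagen, 4 Hox genes and 2 histones were higher. Many ribosomal protein genes have processed pseudogenes, so their values are uncertain.

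Knockout library 7 held more of several germ cell transcripts than the other libraries. Dazl stood at 16154 there and between 6133 and 8502 in the other 5, and Sycp1, of the synaptonemal complex, at 576 against 98.1 to 314. Xist stood at 58.9 in knockout library 7 and 51.3 in knockout library 8, against 4.0 to 12.7 in the other 4.

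The first pattern is the rise of long, AT-rich transcripts and the fall of short, GC-rich ones. Length and GC content also set libraries of 1 genotype apart, accounting for a median of 10.2% (0.5% to 22.3%) of the variance of the difference over the 6 pairs within a group and of 31.6% (19.9% to 43.8%) over the 9 pairs across genotypes, so library differences may account for the 4032 calls that ended with the trend removed: their median absolute log2 change went from 0.49 to 0.13 while the median SE went from 0.11 to 0.09. The fitted trend does not account for every call, since 1653 genes were past the threshold after its removal. Among them were 1083 main calls, chosen for having remained. Their median absolute log2 change went from 0.68 to 0.55 and their median SE from 0.12 to 0.11. Wild-type library 1 alone as the source of the pattern is argued against by wild-type libraries 3 and 4. Length and GC content accounted for 21.3% to 43.8% of the variance of their differences from knockout libraries. Around the mean over libraries, Spearman correlations with length were -0.34 and -0.59 there, against 0.44 to 0.57 in knockout. Without wild-type library 1, 4506 genes changed, a count that does not measure length or GC content. Whether the trend itself comes from genotype stays open, because no batch labels are given and all 3 knockout libraries lie on one side. Of the 10 splits of the libraries, 1 (the real one) gave 5180 changed, 2609 higher and 2571 lower genes, against 0 at most in the others. With the trend removed it gave 1653 against 0. At an unadjusted limma p under 0.05, the other splits gave up to 601 genes, and up to 876 with the trend removed. Each other split mixed the genotypes within its groups, which put their difference into the spread, so 0 calls there does not measure chance. Also, 10 splits are too few for a share under 0.05. For list tests, all 10 gave at least the 2 lists of the real split, and the highest of the others gave 11.

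The second pattern is that wild-type library 1 stood apart from the other wild-type libraries. Muscle genes were higher there by a median of 5.03 (log2; Actc1 9615 against 121 and 206), so skeletal muscle taken along in the dissection is a candidate source for these genes, but not for the male germ cell differentiation list, higher by a median of 1.12, which includes Nanos2 and Tdrd1. The general germ cell list was also higher, by a median of 0.97 (quartiles 0.53 and 1.49), as a larger share of germ cells would give, but a larger share alone is argued against by the pluripotency list, at -0.04 (quartiles -0.31 and 0.34), 1.01 lower; these are spreads over genes in 1 library and not over replicates, the quartiles of the differentiation list (-0.15 and 1.90) do overlap those of the pluripotency list, and a larger share beside another difference stays open. The embryonic globins Hba-x, Hbb-y and Hbb-bh1 had a median difference of -2.10, while the 7 other erythroid genes had a median of 0.54, so a more advanced embryo remains a possible explanation for the germ cell and globin genes. The labels give E13.5 for all libraries, and no biological difference within wild type was tested.

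The third pattern is the lower level of macrophage and complement genes, in a list weighed here because it passed. Its list test is weak evidence, since it was not passed with an estimated correlation, before or after trend removal (adjusted p = 1 and 0.77), and with the preset one it called up to 11 lists in other splits of the libraries. The fitted length and GC trend as the whole cause is argued against by the median over all 15 members in each library, which differed between the groups by -0.71 (SE 0.17) before removal and by -0.42 after it (SE 0.11, n = 3 each, with all knockout libraries at or below -0.12 and all wild-type libraries at or above 0.13 around the mean), and wild-type library 1 alone is argued against by 7 members lower without it and, with the trend also removed, a difference of -0.34 (SE 0.08, 3 members lower). Part of the change did follow the trend, both in the 5 members still past the threshold (median log2 change from -1.09 to -0.53, SE 0.14 and 0.13) and in the 4 whose call ended (-0.85 to -0.49, SE 0.22 and 0.19; Fcer1g, Fcgr1, Lyz2 and Tyrobp, named after their values were seen). After trend removal 14 of 15 members had a lower mean in knockout, with a range from -0.70 to 0.07. The members are not independent replicates and the list was chosen because it passed, so this count is no separate evidence. Mrc1 and Ptprc were lower only after removal (log2 0.133 to -0.307, SE 0.193 after, and 0.081 to -0.359, SE 0.255 after). Fewer macrophages in the knockout gonads may account for the rest of the change. This is a hypothesis beside lower transcription in as many cells, which was not tested, and genotype, which stays open.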
